A study of Mus musculus with 6 samples.

How the data were processed

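The values are the authors' deposited gene-level read counts for endometrium of 6 ICR mouse libraries, 3 with and 3 without GnRH agonist treatment, in 1 table with a row per gene symbol and a column per library. Per the labels' protocols, tamoxifen was given to newborn females to induce adenomyosis, histology served for the diagnosis, the agonist or its solvent was injected into the abdomen, and total RNA with an integrity number above a set minimum was made into libraries with the Ion Total RNA-Seq Kit and sequenced single-end on an Ion Proton. Per the submitters' processing notes, reads were placed on the mouse genome build mm10 (GRCm38) and counted with HTSeq 0.6.1. The aligner, the gene annotation, the strand setting and any filter are not given in the sources used here. The deposited counts are whole numbers, and no normalization by the authors is recorded for them. Every column was mapped to a sample from the labels. The labels give no litter, batch or day and share no replicate numbers between the groups, so no paired analysis was made.

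The depth ranged from 11720958 to 14104266 counts per library, and a count of 0 allows up to 3 counts of the total. Shares of a single library carry exact (Clopper-Pearson) 95% binomial intervals. Symbols were looked up by exact match in the GENCODE M21 annotation of GRCm38, which held 31006.0 of the 44788 symbols and 15184 of the 16581 tested. Coordinates are from that annotation, 1-based. The annotation used for the counting may have differed from it, and older symbols such as Clca3 were kept as deposited.

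All computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr at its default settings, libraries scaled by TMM factors, and the agonist group was compared with the group without it by edgeR's quasi-likelihood F-test without further covariates. Calls needed a Benjamini-Hochberg adjusted p under 0.05 over the 16581 genes tested. The common biological coefficient of variation was 0.375 and the prior degrees of freedom 3.65. Levels are CPM with TMM-scaled library sizes, given as mean ± SD over 3 libraries, and log2 fold changes are agonist over no agonist with their standard errors.

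The 39 gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it with camera with an estimated correlation and with fry, each adjusted over the lists. A list needed 3 tested members. Its mean log2 difference is the mean over members of the difference between group means of log2 CPM, and its level per library is the mean over members after centring each gene on the 6 libraries. These levels were compared with an exact two-sided permutation test, whose smallest possible p is 0.1 with 3 against 3. The lists covered regulators of receptivity, progesterone-induced, estrogen-induced and decidualization genes, and markers of uterine glands, epithelium, endometrial stroma, smooth muscle, endothelium, NK and T cells, macrophages and dendritic cells, neutrophils, B and plasma cells, mast cells, red blood cells, mesothelium, fat cells, ovary and oviduct, and embryo and trophoblast. They also covered the cell cycle, extracellular matrix, epithelial-mesenchymal transition, interferon-stimulated genes, MHC class II, inflammatory cytokines, prostaglandins, ion and water transport, steroid receptors and metabolism, Hox genes, integrins, Wnt and hedgehog signalling, immediate early genes, hypoxia and glycolysis, cholesterol synthesis, antioxidants, the respiratory chain, ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. Several lists share members, and many of the marker genes are also expressed by other cells of the endometrium.

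Genes were named by 4 rules. The first took up to 12 genes per direction with the largest log2 fold change among those past the threshold, with a mean of at least 5 CPM and separated groups, filled up to 5 by the smallest p where fewer than 5 passed. The second named Lif, Ihh, Hoxa10, Hoxa11, Itgb3, Areg, Hbegf, Msx1, Bmp2, Wnt4, Hand2, Esr1, Pgr, Ltf, Muc1, Gnrhr and Mki67 whatever their values. The third took up to 4 members of each list with the smallest p, fewer where the text would repeat itself, and the fourth the 5 genes with the highest mean CPM. The groups, the main test, the lists, these rules and the alternatives below, save those named as chosen later, were fixed before the data were examined. Which of the third rule's genes are described was narrowed after their values were seen, and Dio3 was added then. Some genes that the third rule names are not reported.

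The test was tried on simulated data with the means and library sizes of this comparison, changed by 2-fold in 100 genes and by 4-fold in 100 others. At the dispersions observed here, over 16301 genes, it recovered 4 of the 100 genes changed 2-fold and 65 of the 100 changed 4-fold, with 7 false calls. At a dispersion of 0.02, over 16440 genes, it recovered 99 and 100, with 8 false calls. A simulated list of 20 genes shifted by 1 on the log2 scale gave a mean log2 difference of 1.13, and an unshifted list gave a camera p of 0.951, both over 16581 genes. The simulated genes were drawn independently, so these lists cannot show how often correlated lists are falsely called. Among the called lists the estimated correlation ran from -0.0185 for B and plasma cell markers to 0.900 for smooth muscle markers.

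The alternatives for genes were RLE factors, upper-quartile factors, library totals alone, no filter beyond 1 read, a filter at 5 CPM in 3 libraries, DESeq2's Wald test, limma-voom with and without quality weights, edgeR's likelihood ratio test, robust dispersions, a minimum fold of 2 and leaving out each library in turn. For lists they were the estimated correlation, fry, library totals alone, RLE factors, the stricter filter, a prior count of 0.5, voom values and weights, and leaving out each library. Chosen after seeing the data were edgeR's bias-adjusted quasi-likelihood fit, the counts without Rn18s-rs5, the comparison without the 2 libraries rich in 18S, and the smooth muscle level as a covariate.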

Results

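The series measured gene expression in the endometrium, the inner lining of the uterus, of mice with adenomyosis, a condition in which endometrial glands and stroma lie within the muscle wall. Female mice of the outbred ICR strain had received tamoxifen by mouth at 2.7 µmol/kg on days 2 to 5 after birth. After 75 days, 8 mice received the GnRH agonist Decapeptyl (triptorelin) at 1.5 µg per 100 g per day on days 3 to 9 of estrus, and 8 mice received solvent. Given over days, a GnRH agonist first stimulates and then suppresses the pituitary signal to the ovary. The mice were mated 4 weeks later, and endometrium was scraped from the uterus on day 4 of pregnancy, close to the time at which the mouse uterus becomes receptive to embryos. The 6 libraries comprised 3 of the agonist group and 3 of the group without agonist. The labels do not tie a library to a single mouse, so p-values measure the spread between these libraries.

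The table listed 44788 genes, of which 28089 had a read and 16581 had enough reads to be tested. Library totals were 13137470, 12520684 and 12053447 counts without the agonist and 12220461, 14104266 and 11720958 counts with it. In such libraries 3 counts corresponded to 0.213 to 0.256 CPM (counts scaled to library size). The 18S ribosomal RNA gene Rn18s-rs5 took 3.31% of the counts in no-agonist library 2 (95% exact binomial interval 3.30 to 3.32%) and 1.94% in agonist library 1 (1.94 to 1.95%). The other libraries gave 0.254 to 0.369%. Mitochondrially encoded messages made up 1.22% in no-agonist library 1 (1.22 to 1.23%) and 3.89% in agonist library 1 (3.88 to 3.90%), the lowest and highest shares of the 6. Intervals and floors cover counting error alone. Spearman correlations of log2 CPM across genes, which are not independent replicates, ranged from 0.936 to 0.963 within the group without agonist and from 0.939 to 0.947 within the agonist group. Between the groups they ranged from 0.894, for no-agonist library 3 and agonist library 2, to 0.961, for no-agonist library 1 and agonist library 1. The latter lay above every pair within the agonist group, so these correlations did not group the libraries by treatment. By mean CPM the most abundant genes were Rn18s-rs5, the mitochondrial COX1, the translation factor Eef1a1, C3 and Gm13456. Gm13456 is annotated as a processed pseudogene (chromosome 2, 40555752 to 40557116, GRCm38), so its counts and those of a parent gene may be shared.

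The comparison asked how GnRH agonist treatment before pregnancy altered the endometrial transcriptome at the time of receptivity in this model. The homeobox gene Msx1, a transcription factor of the uterus before implantation, measured 351 ± 105 against 86.0 ± 9.76 CPM (mean ± SD in the agonist group against the group without it, n = 3 each, as for all levels that follow). That was a 4.08-fold higher level in which all 3 agonist libraries lay above all 3 others. Estrogen-induced genes, such as complement C3 and the deiminase Padi2, were lower as a list (adjusted p = 2.02e-08, and adjusted p = 0.797 with an estimated correlation). Epithelial and smooth muscle markers were also lower as lists, and cell cycle genes and markers of NK, T, B, plasma and endothelial cells were higher. Over all 12 called lists the smallest adjusted p = 0.797 with an estimated correlation. No single gene passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. It found 0 genes higher and 0 lower, with a smallest adjusted p of 0.156, while 691 genes lay higher and 844 lower at an unadjusted p under 0.05. The 3 libraries of one group lay entirely above the other group for 1150 genes and entirely below for 1262, together 14.5% of the genes tested where chance gives 10%. Of the other splits of the 6 libraries into 3 and 3, the highest separated 2585 genes, against 2412 here. DESeq2 called 166 genes higher and 255 lower, edgeR's likelihood ratio test 104 and 164, and limma-voom 0 and 0. With library totals alone in place of TMM factors the unadjusted counts were 1192 higher and 520 lower, and the median log2 fold change of all genes moved from 0.018 to 0.183. With upper-quartile factors they were 826 and 700.

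Among genes whose libraries separated and whose mean was at least 5 CPM, the smallest p-values toward lower levels belonged to 5 genes that did not pass the adjusted threshold. Mgat4c, an enzyme of the N-glycan branching family (chromosome 10, 101681487 to 102391469, GRCm38), measured 0.480 ± 0.122 against 24.9 ± 12.7 CPM, a 51.2-fold lower level (log2 fold change -5.68 ± 0.58 SE, adjusted p = 0.156). Without no-agonist library 2 its adjusted p was 0.0195, the 1 gene past the threshold in that fit, and over its alternatives it ranged from 4.46e-18 with DESeq2 to 0.474 without no-agonist library 3. Its family member Mgat4a (chromosome 1, 37439340 to 37541016) measured 17.8 ± 6.51 against 108 ± 5.12 CPM (log2 fold change -2.60 ± 0.30, adjusted p = 0.195). The receptor-type tyrosine phosphatase Ptpro (chromosome 6, 137252319 to 137463233) measured 4.14 ± 0.556 against 24.1 ± 3.74 CPM (log2 fold change -2.54 ± 0.27, adjusted p = 0.156). The cell adhesion molecule Ceacam1 (chromosome 7, 25461707 to 25477603) measured 34.0 ± 20.2 against 327 ± 22.7 CPM, a 9.62-fold lower level (adjusted p = 0.209). Reads of Ceacam1 can be shared with its close paralog Ceacam2. The noncoding Dio3os (chromosome 12, 110275385 to 110278172) measured 5.14 ± 1.27 against 54.1 ± 30.1 CPM (log2 fold change -3.40 ± 0.44, adjusted p = 0.209). In the GENCODE M21 annotation it lies 895 bases from the oppositely oriented Dio3, the thyroid hormone-inactivating deiodinase, which measured 2.14 ± 0.846 against 13.3 ± 4.97 CPM and was looked up after the values were seen. The strand setting and annotation behind the counts are not given in the sources used here, so the assignment of reads between this pair is uncertain.

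Toward higher levels, the smallest p-values belonged to Msx1 (chromosome 5, 37820485 to 37824583; log2 fold change 2.03 ± 0.28, adjusted p = 0.209) and 4 further genes. Tspan15, a tetraspanin partner of the membrane protease ADAM10 (chromosome 10, 62185396 to 62231251), measured 21.1 ± 6.07 against 3.28 ± 0.963 CPM, 6.42-fold higher (log2 fold change 2.68 ± 0.36, adjusted p = 0.209). The secreted phospholipase Pla2g5 (chromosome 4, 138799244 to 138863482) measured 20.8 ± 9.62 against 2.35 ± 0.687 CPM (log2 fold change 3.14 ± 0.48, adjusted p = 0.209). Pik3ap1, an adapter of phosphoinositide 3-kinase signalling (chromosome 19, 41272377 to 41385102), measured 44.5 ± 7.33 against 17.6 ± 1.15 CPM, and Nrep (chromosome 18, 33437019 to 33464029) measured 124 ± 26.1 against 41.9 ± 9.25 CPM, each with adjusted p = 0.209. All 10 of these genes are annotated as protein-coding except Dio3os, and all 10 were called by DESeq2, with adjusted p from 4.46e-18 for Mgat4c to 1.62e-04 for Pik3ap1. They were picked by p from the same counts, so DESeq2's calls are no independent support.

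**Figure D1:**
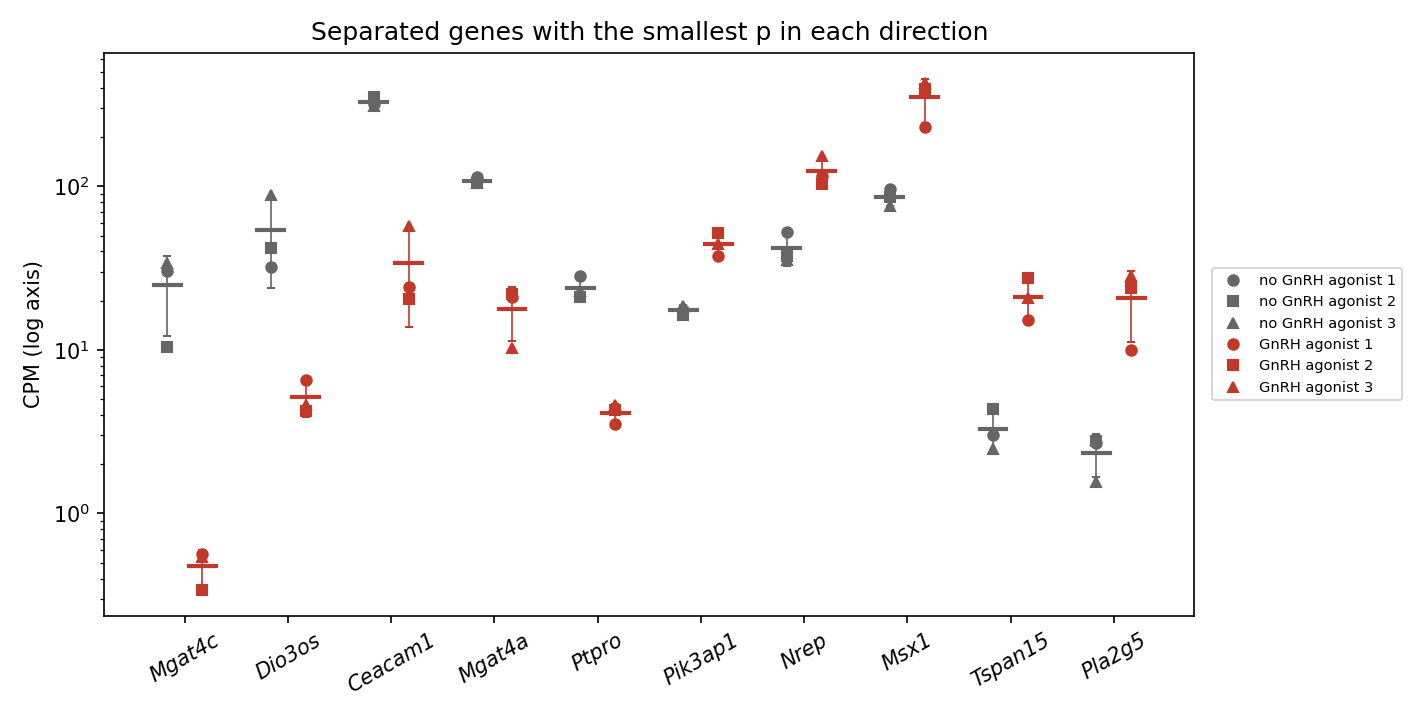
CPM on a log axis in each of the 6 libraries for the 5 separated genes with the smallest p in each direction; points are libraries, thick bars group means and thin bars SD (n = 3). Msx1 lies between 76.3 and 95.9 CPM without the agonist and between 231 and 429.8 CPM with it, and none of the 10 genes passed the adjusted threshold of edgeR's quasi-likelihood test.

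Of the receptivity regulators, 14 of 26 tested lay higher and 12 lower, with 4 higher when adjusted over the list alone and 0 over all genes tested (list adjusted p = 0.291; adjusted p = 0.882 with an estimated correlation). Beside Msx1, these were the cyclooxygenase gene Ptgs1 at 39.7 ± 9.51 against 14.7 ± 2.58 CPM, the LIF receptor Lifr at 46.9 ± 19.9 against 18.2 ± 3.76 CPM and the lysophosphatidic acid receptor Lpar3 at 16.2 ± 5.93 against 4.39 ± 2.29 CPM. The implantation cytokine Lif itself measured 9.01 ± 5.86 against 21.5 ± 15.9 CPM (log2 fold change -1.26 ± 0.63, adjusted p = 0.601). Hoxa10 measured 83.1 ± 34.6 against 76.1 ± 44.1 CPM and Hoxa11 72.6 ± 33.2 against 63.3 ± 25.7 CPM, with log2 fold changes of 0.13 ± 0.48 and 0.20 ± 0.42 that were smaller than their errors. Log2 fold changes were -0.32 ± 0.30 for the integrin Itgb3, -0.31 ± 0.28 for the growth factor Hbegf, 0.99 ± 0.49 for Bmp2, -0.72 ± 0.38 for Wnt4 and 0.43 ± 0.49 for Hand2, none of them past the threshold. Areg, with 5 reads in all, and the GnRH receptor Gnrhr, with 0 reads, were not tested. A count of 0 allows up to 0.213 to 0.256 CPM. The estrogen receptor Esr1 measured 307 ± 44.1 against 282 ± 5.72 CPM, and the progesterone receptor Pgr 106 ± 45.7 against 117 ± 32.0 CPM.

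Progesterone-induced genes were higher as a list, with 12 of 16 tested members higher (adjusted p = 0.0147, 0.00246 to 0.882 over its alternatives), a call that was lost in a second form of the test (adjusted p = 0.882 with an estimated correlation). When adjusted over the list alone 2 members passed, and 0 over all genes tested. These were the endocytic receptor Lrp2 at 17.1 ± 23.7 against 0.517 ± 0.388 CPM, with 44.4 CPM in agonist library 2, and the retinoic acid-degrading Cyp26a1 at 4.64 ± 1.16 against 0.493 ± 0.621 CPM. The transcription factor Sox17 measured 181 ± 42.0 against 102 ± 22.4 CPM and the lipoxygenase Alox15 269 ± 30.3 against 127 ± 57.5 CPM. The epithelial hedgehog ligand Ihh measured 16.9 ± 12.2 against 3.39 ± 3.79 CPM (log2 fold change 2.30 ± 0.98, adjusted p = 0.535). The list's call also ended without no-agonist library 2 (adjusted p = 0.121), without agonist library 2 (adjusted p = 0.102) and with the stricter filter on low counts (adjusted p = 0.211, mean log2 difference 0.48 against 0.85). Decidualization genes were not called (adjusted p = 0.644; mean log2 difference -0.13 and median fitted log2 fold change 0.11, opposite in sign). In that list the alkaline phosphatase Alpl measured 68.8 ± 32.8 against 438 ± 55.2 CPM (adjusted p = 0.209), the 1 member past the threshold adjusted over the list alone.

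Estrogen-induced genes lay lower in 16 of 17 tested members, with a median fitted log2 fold change of -1.88 and 10 members lower when adjusted over the list alone but 0 over all genes tested. The list holds several Sprr2 and several Padi genes, close relatives between which reads can be shared. Its members are therefore not independent. The list was called lower (adjusted p = 2.02e-08, 8.76e-12 to 0.797 over its alternatives), a call that was lost in the second form of the test (adjusted p = 0.797 with an estimated correlation). The deiminases Padi2 and Padi1 measured 431 ± 219 against 1923 ± 227 CPM, and 1181 ± 392.3 against 3896 ± 1296 CPM. C3 measured 1733 ± 874 against 6733 ± 3062 CPM, and Clca3, an older symbol of the secreted epithelial protein Clca1, 1153 ± 888 against 7063 ± 4488 CPM. The surface mucin Muc1 measured 360.2 ± 197 against 799 ± 65.3 CPM (adjusted p = 0.437). Lactotransferrin, Ltf, a classic estrogen-responsive gene, varied within groups, from 839 to 7098 CPM without the agonist and from 29.2 to 5361 CPM with it (log2 fold change -0.20 ± 1.37). The list's level was 0.14, 0.31 and 1.99 in the libraries without agonist and 0.23, -0.66 and -2.01 with it, on a log2 scale centred on all 6, so agonist library 1 overlapped the other group (exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). The mean log2 difference of -1.63 was -1.04 without no-agonist library 3 and -0.97 without agonist library 3. Smooth muscle marker levels were 0.14, -0.10 and 1.49 without the agonist and 0.59, -1.13 and -0.99 with it.

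Epithelial markers lay lower in 15 of 18 tested members (adjusted p = 2.31e-04, 8.85e-05 to 0.797 over its alternatives; adjusted p = 0.797 with an estimated correlation), and all 3 agonist libraries lay below the others (exact permutation p = 0.1). The keratin Krt7 measured 565 ± 243 against 2053 ± 660.1 CPM and Krt19 956 ± 94.4 against 2121 ± 768 CPM. When adjusted over the list alone 2 members were lower, Krt7 among them, and 0 over all genes tested. With library totals alone the list's mean log2 difference was -0.27 against -0.44. Integrins and their ligands were lower in 16 of 20 tested members (adjusted p = 0.00685, 9.33e-04 to 0.882 over its alternatives; adjusted p = 0.882 with an estimated correlation). Itgb6 measured 25.8 ± 2.35 against 47.3 ± 5.82 CPM and Itgb4 144 ± 36.6 against 289 ± 29.99 CPM, both past the threshold adjusted over the list alone. That list's call ended without no-agonist library 3 (adjusted p = 0.221, mean log2 difference -0.15 against -0.41) and without agonist library 3 (adjusted p = 0.0767, -0.24), and with library totals alone its mean was -0.24. Uterine gland markers were not called (adjusted p = 0.524, 0.00481 to 0.949 over its alternatives) until agonist library 1 was left out (adjusted p = 0.0340). Cxcl15, a chemokine of uterine glands, measured 1.36, 82.2 and 69.8 CPM in the agonist libraries and 0.5996 ± 0.539 CPM without the agonist. Of the 8 listed gland genes 4 were tested, with 3 higher and 1 lower. Aldh1a1 measured 56.9 ± 42.8 against 16.4 ± 7.68 CPM, Foxa2 14.5 ± 6.37 against 13.9 ± 4.11 CPM and Prom1 302 ± 171 against 532 ± 323 CPM.

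Smooth muscle markers lay lower in 16 of 16 tested members without a member at an unadjusted p under 0.05 (adjusted p = 3.00e-05, 4.04e-11 to 0.923 over its alternatives; adjusted p = 0.882 with an estimated correlation). Desmin, Des, measured 444 ± 254 against 1187 ± 929.6 CPM, and Csrp1 685 ± 269 against 1428 ± 839.9 CPM. The list's mean log2 difference of -1.02 was -0.53 without no-agonist library 3, the library with the highest level, and -1.56 without agonist library 1, whose level of 0.59 lay above no-agonist libraries 1 and 2. Hypoxia and glycolysis genes were lower in 19 of 20 members (adjusted p = 2.31e-04, 1.40e-06 to 0.923 over its alternatives; adjusted p = 0.882 with an estimated correlation). The glycolytic enzyme Eno1 measured 97.1 ± 27.8 against 177 ± 57.2 CPM, and the oxygen-sensing Egln3 19.7 ± 9.97 against 121 ± 160.2 CPM. No-agonist library 3 held the highest level of this list too, 1.37, and without it the mean log2 difference was -0.14 against -0.67 (adjusted p = 0.260). Cholesterol synthesis genes lay lower in 17 of 19 members (adjusted p = 0.00802, 4.44e-07 to 0.995 over its alternatives; adjusted p = 0.949 with an estimated correlation). This call ended without no-agonist library 2 (adjusted p = 0.790, mean log2 difference -0.062 against -0.46), without agonist library 1 (adjusted p = 0.0822) and without agonist library 3 (adjusted p = 0.1298, -0.26). Without no-agonist library 1 and without agonist library 2 the mean was -0.85 and -0.69, and with library totals alone -0.29.

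NK and T cell markers were higher in 9 of 9 tested members (adjusted p = 1.96e-04, 1.23e-06 to 0.797 over its alternatives; adjusted p = 0.797 with an estimated correlation), none with a mean over the 6 libraries above 6.90 CPM. The cytokine receptor Il2rb measured 9.42 ± 5.56 against 3.15 ± 0.743 CPM, and the NK receptor Ncr1 2.99 ± 2.44 against 0.646 ± 0.424 CPM. B and plasma cell markers were higher in 5 of 6 members (adjusted p = 0.00513, 6.08e-04 to 0.797 over its alternatives; adjusted p = 0.797 with an estimated correlation). Of them, 4 were higher when adjusted over the list alone and 0 over all genes tested. Mzb1 of plasma cells measured 6.43 ± 3.21 against 1.61 ± 0.611 CPM, the B cell receptor component Cd79a 3.39 ± 1.73 against 0.7995 ± 0.405 CPM and the light chain gene Igkc 232 ± 129 against 83.2 ± 23.3 CPM. The 3 agonist libraries lay above the other 3 in both lists (exact permutation p = 0.1). With the stricter filter the B and plasma cell list was no longer called (adjusted p = 0.211). Endothelial markers were higher in 14 of 14 members (adjusted p = 0.00911, 5.09e-05 to 0.882 over its alternatives; adjusted p = 0.882 with an estimated correlation). The sialomucin Emcn measured 44.2 ± 15.0 against 24.7 ± 1.52 CPM, and the cadherin Cdh5 60.2 ± 24.5 against 33.6 ± 8.23 CPM. This call ended without no-agonist library 3 (adjusted p = 0.0541), agonist library 1 (adjusted p = 0.181) or agonist library 2 (adjusted p = 0.0572), and the mean log2 difference without agonist library 1 was 0.28 against 0.39. Macrophage and dendritic cell markers were not called (adjusted p = 0.710, 7.21e-05 to 0.983 over its alternatives), although without no-agonist library 2 they were lower (adjusted p = 7.21e-05). In that list the lysosomal protein Cd68 measured 19.6 ± 6.23 against 60.7 ± 23.2 CPM (log2 fold change -1.63 ± 0.36, adjusted p = 0.266). Neutrophil (adjusted p = 0.904), mast cell (adjusted p = 0.395, 0.0138 to 0.950 over its alternatives) and red blood cell markers (adjusted p = 0.717) were not called. The mast cell list had a mean log2 difference of 0.73 with a median fitted log2 fold change of -0.01. Without no-agonist library 3 the mast cell list was called higher (adjusted p = 0.0138).

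Cell cycle genes were higher in 29 of 29 members, with a median fitted log2 fold change of 1.09 (adjusted p = 2.00e-05, 1.99e-14 to 0.944 over its alternatives; adjusted p = 0.944 with an estimated correlation). Bub1b of the mitotic checkpoint measured 41.8 ± 29.9 against 14.7 ± 7.05 CPM and the spindle protein Nusap1 24.5 ± 16.3 against 9.33 ± 4.71 CPM. The proliferation marker Mki67 measured 81.3 ± 45.4 against 35.5 ± 27.6 CPM (log2 fold change 1.20 ± 0.60, adjusted p = 0.601). The list's level ranged from -1.43 to 0.30 without the agonist and from -0.57 to 1.56 with it, and the call ended without no-agonist library 3 (adjusted p = 0.0595, mean log2 difference 0.44 against 0.92) or agonist library 2 (adjusted p = 0.106, 0.37). Without agonist library 3 the mean was 1.44. Genes of Wnt and hedgehog signalling were higher in 20 of 23 members (adjusted p = 0.00153, 7.67e-06 to 0.882 over its alternatives; adjusted p = 0.882 with an estimated correlation). Wnt11 measured 2.62 ± 1.35 against 0.392 ± 0.447 CPM and the Wnt receptor Fzd6 131 ± 38.0 against 74.5 ± 12.8 CPM. The hedgehog receptor Ptch1 measured 44.9 ± 15.2 against 26.2 ± 4.34 CPM. This list's mean log2 difference of 0.74 was 1.12 without no-agonist library 1 and 0.48 without agonist library 3.

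**Figure D2:**
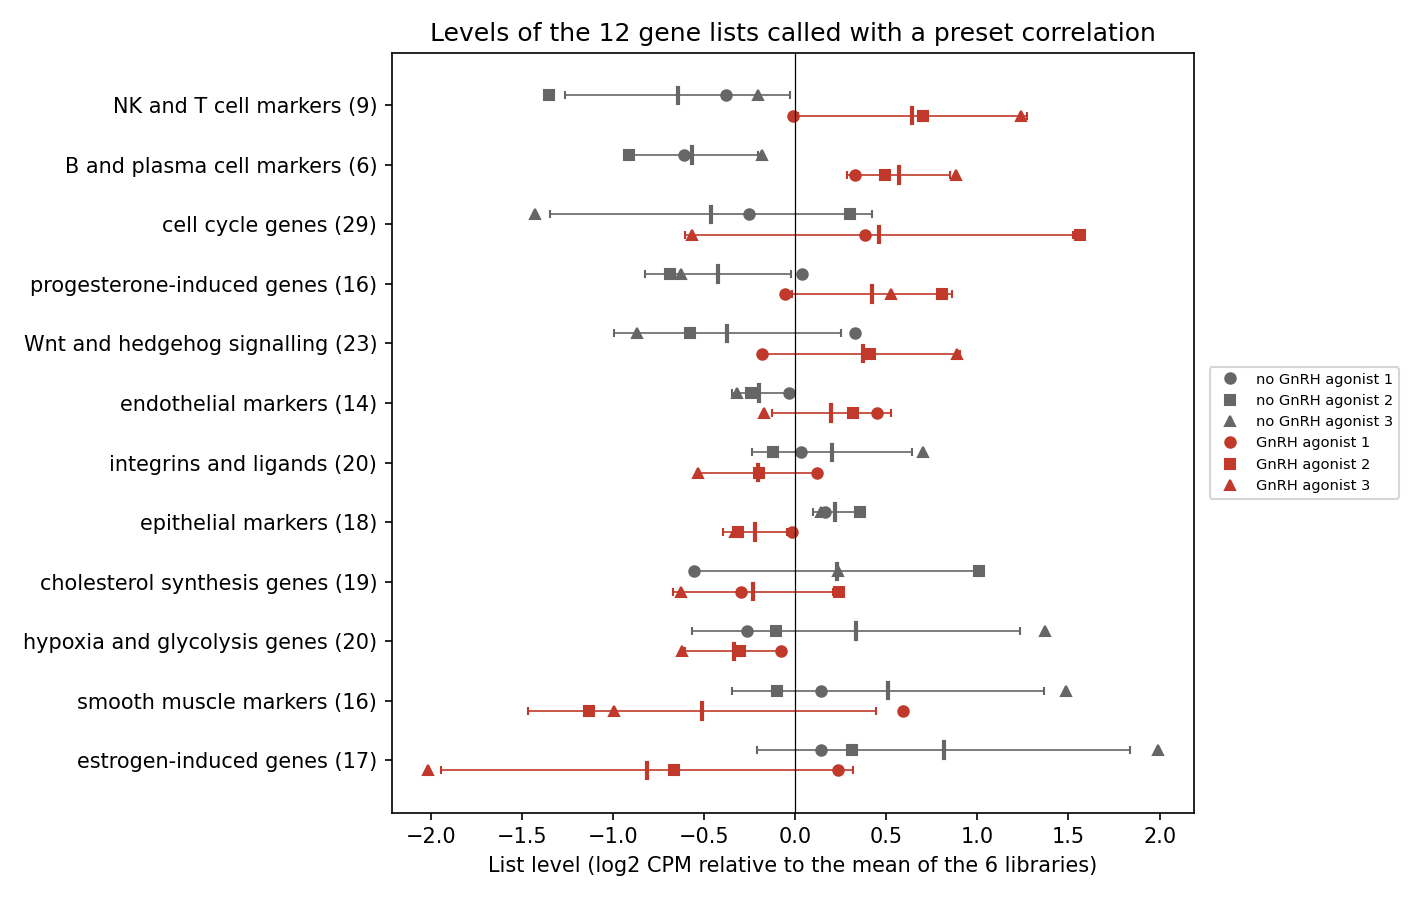
Level of each of the 12 gene lists called by camera with a preset correlation of 0.01 in each library, as the mean over tested members (number in brackets) of log2 CPM minus the mean of the 6 libraries; points are libraries, thick bars group means and thin bars SD (n = 3). The groups separate in 3 of the lists (epithelial, NK and T cell, B and plasma cell), and no call held with an estimated correlation.

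The remaining lists were not called with all 6 libraries. Endometrial stroma markers (adjusted p = 0.736), Hox genes (adjusted p = 0.239), prostaglandin synthesis and receptors (adjusted p = 0.504), steroid receptors and metabolism (adjusted p = 0.710), epithelial-mesenchymal transition factors (adjusted p = 0.504), antioxidant and metallothionein genes (adjusted p = 0.813), respiratory chain genes (adjusted p = 0.736) and replication-dependent histones (adjusted p = 0.710) kept that result when each library was left out in turn. Within them, 3 prostaglandin genes were higher and 1 lower when adjusted over the list alone: besides Ptgs1 and Lpar3, the prostaglandin E receptors Ptger2 at 3.38 ± 0.770 against 0.705 ± 0.517 CPM and Ptger4 at 49.9 ± 6.48 against 93.5 ± 27.2 CPM. The membrane estrogen receptor Gper1 measured 16.3 ± 9.91 against 3.05 ± 1.85 CPM and the steroid dehydrogenase Hsd17b2 0.727 ± 0.908 against 11.3 ± 12.5 CPM. The cadherin Cdh2 measured 6.29 ± 3.82 against 1.77 ± 0.724 CPM. The peroxidase Gpx1 measured 498 ± 269 against 1224 ± 108 CPM, and the glutathione transferase Gstm1 178 ± 107 against 75.5 ± 20.9 CPM. Ion, water and calcium transport genes (adjusted p = 0.254, 0.0150 to 0.923 over its alternatives) had a mean log2 difference of -0.30 and a median fitted log2 fold change of 0.06. In this list the chloride channel Cftr measured 44.2 ± 10.0 against 108 ± 43.2 CPM and the calcium channel Trpv6 175 ± 113 against 529.8 ± 237 CPM. The list was called lower without no-agonist library 2 (adjusted p = 0.0150) or agonist library 2 (adjusted p = 0.0267). Extracellular matrix genes (adjusted p = 0.177, 9.33e-04 to 0.954 over its alternatives) were called lower without no-agonist library 2 (adjusted p = 0.00141) and with library totals alone (adjusted p = 0.0453). The crosslinking enzyme Lox measured 24.5 ± 6.83 against 60.1 ± 33.2 CPM, and Tgfbi 413 ± 288 against 64.1 ± 44.7 CPM. Inflammatory cytokines and chemokines (adjusted p = 0.554, 0.00767 to 0.954 over its alternatives), among them the inhibitor Nfkbia at 185 ± 60.3 against 393 ± 138 CPM, were called lower without the same library (adjusted p = 0.00767).

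Interferon-stimulated genes (adjusted p = 0.612, 1.34e-05 to 0.954 over its alternatives) turned with single libraries: they were called higher without no-agonist library 3 (adjusted p = 0.0138, mean log2 difference 0.51) and lower without no-agonist library 2 (adjusted p = 0.00254, -0.64) or agonist library 1 (adjusted p = 0.0356). MHC class II genes (adjusted p = 0.524, 0.0309 to 0.954 over its alternatives; mean log2 difference 0.28, median fitted log2 fold change -0.11) and mitochondrially encoded genes (adjusted p = 0.373, 0.0194 to 0.997 over its alternatives) were called higher without no-agonist library 3 (adjusted p = 0.0398 and 0.0194). Ribosomal protein genes, whose reads can be shared with many pseudogenes, were not called (adjusted p = 0.0676, 7.21e-05 to 0.949 over its alternatives) but were called higher without no-agonist library 2 (adjusted p = 7.21e-05). They were also called with library totals alone (adjusted p = 0.0278), the stricter filter (adjusted p = 0.0293) or voom weights (adjusted p = 0.0366). Among them Rps19 measured 331 ± 112 against 167 ± 64.2 CPM. Immediate early genes were not called (adjusted p = 0.833), with a mean log2 difference of 0.07 and a median fitted log2 fold change of -0.26. Their member Klf4 measured 221 ± 36.1 against 416 ± 119 CPM. Of tissues that scraping can carry along, fat cell (adjusted p = 0.904), mesothelial (adjusted p = 0.710), ovary and oviduct (adjusted p = 0.683) and embryo and trophoblast markers (adjusted p = 0.914) were not called. The test's direction for the fat cell list was lower while its mean log2 difference was 0.40. The mesothelial list had a mean log2 difference of 0.06, a median log2 difference of -0.25 and a median fitted log2 fold change of 0.37, with 7 of 7 fitted values higher. The ovary and oviduct list had 0.98, -0.10 and -0.0392 for these measures, with 1 of 3 higher. The fat cell secretory gene Cfd measured 0.261 CPM in no-agonist library 2 and 0 CPM in agonist library 2, against 74.8 to 496 CPM in the other libraries. The oviduct glycoprotein Ovgp1 measured 173 CPM in agonist library 1, 14.2 and 3.85 CPM in the other agonist libraries and 2.25 ± 0.920 CPM without the agonist.

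Leaving out the 2 libraries rich in 18S, no-agonist library 2 and agonist library 1, was chosen after seeing the data. Brackets give each list's adjusted p and mean log2 difference without them. Only 2 libraries per group remained, and the calls used the preset correlation. Endothelial markers (adjusted p = 0.232, 0.26) and cholesterol synthesis genes (adjusted p = 0.995, -0.024) were then not called. The mean log2 differences of other called lists grew to -1.87 for smooth muscle markers, -1.01 for hypoxia and glycolysis genes and -0.73 for integrins and ligands. In these lists agonist library 1 held the highest level of its group (0.59, -0.08 and 0.12). Leaving it out widens these differences whatever its 18S share. Among lists not called with all 6 libraries, uterine gland markers (adjusted p = 0.00481, 2.51), red blood cell markers (adjusted p = 0.0389, 1.85) and ribosomal protein genes (adjusted p = 5.21e-04, 0.42) were then called higher. Macrophage and dendritic cell (adjusted p = 0.00108, -0.77), mesothelial (adjusted p = 0.00290, -1.89) and fat cell markers (adjusted p = 0.00900, -2.65) were called lower. So were extracellular matrix (adjusted p = 9.33e-04, -0.59), interferon-stimulated (adjusted p = 1.34e-05, -1.01) and MHC class II genes (adjusted p = 0.0309, -0.62). Inflammatory cytokines and chemokines (adjusted p = 0.0123, -0.83), ion, water and calcium transport (adjusted p = 0.0237, -0.75) and immediate early genes (adjusted p = 0.0265, -0.82) were called lower as well. For fat cell and red blood cell markers the levels, centred on all 6 libraries, overlapped between the remaining libraries of the groups. Fat cell levels were 2.31 and 0.85 without the agonist, and -4.24 (agonist library 2) and 2.12 with it. Red blood cell levels were 0.47 and -2.23 without the agonist and -0.44 and 1.34 with it. Over all alternatives, the red blood cell, mesothelial, fat cell and immediate early lists had adjusted p-values of up to 0.954, 0.954, 0.957 and 0.967.

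Single genes were tested with edgeR's quasi-likelihood test over 16581 genes and lists with camera over 39 lists, both with Benjamini-Hochberg adjustment. With an estimated correlation 0 of the 12 called lists held, the smallest adjusted p being 0.797, and 0 passed fry's directional test after adjustment. For B and plasma cell markers the estimated correlation was -0.0185, below the preset 0.01. Their unadjusted camera p still rose from 0.00105 with the preset to 0.0284 with the estimated correlation. A higher correlation between genes therefore does not account for the loss of that call. The form with an estimated correlation thus differs from the preset form in more than the correlation. Its lost calls cannot be put down to correlated members alone. Without the 2 libraries rich in 18S the test called 0 genes higher and 7 lower, with 719 and 1187 at an unadjusted p under 0.05, and camera called 8 lists higher and 14 lower.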

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

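Chosen after the results were seen were the bias-adjusted fit, the counts without Rn18s-rs5, the comparison without the 2 libraries rich in 18S and the smooth muscle covariate. The number of genes past the threshold in edgeR's quasi-likelihood test, 0 higher and 0 lower, was the same with RLE and upper-quartile factors, library totals alone, the stricter filter, limma-voom with and without quality weights, robust dispersions, a minimum fold of 2, the bias-adjusted fit, the counts without Rn18s-rs5 and the covariate. At an unadjusted p under 0.05 these, save the minimum fold, gave 508 to 1192 genes higher and 520 to 879 lower. The minimum fold only selects among the genes of the main test, so its 0 and 0 were fixed in advance. At an unadjusted p under 0.05 it kept 412 higher and 425 lower. It was 8 higher and 28 lower with no filter on low counts, 166 and 255 with DESeq2, 104 and 164 with the likelihood ratio test, and 0 and 7 without the 2 libraries rich in 18S. Leaving out each library gave 0 to 0 higher and 0 to 1 lower, the 1 being Mgat4c without no-agonist library 2. Of DESeq2's 421 calls, 401 were among the genes edgeR tested, and all 401 had the same direction and an unadjusted edgeR p under 0.05. Both methods used the same counts, so this overlap is no independent support. The list counts of 6 higher and 6 lower were 0 and 0 with an estimated correlation and with fry, and 8 and 14 without the 2 libraries rich in 18S. Leaving out each library gave 3 to 8 lists higher (3 without agonist library 2) and 4 to 10 lower (10 without no-agonist library 2). The cause of these differences was not tested, except that leaving out libraries leaves fewer samples.

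For named genes, the alternatives counted here leave out the stricter filter, limma-voom quality weights, the likelihood ratio test and the minimum fold. Over the others the named genes gave 1256 values with the same direction and side of the threshold, 47 that came past it and 22 of opposite sign. The likelihood ratio test, not counted here, also brought named genes past it, such as Msx1 (adjusted p = 3.70e-06). Over all their alternatives the lists gave 469 values with the same result, 24 that came past the threshold and 41 that no longer passed. A further 45 were of opposite sign, none of them from a list called with all 6 libraries. Mean log2 differences of opposite sign were, with library totals alone, 0.071 for macrophage and dendritic cell markers, 0.076 for embryo and trophoblast markers, 0.033 for decidualization genes, 0.042 for interferon-stimulated genes and 0.13 for respiratory chain genes. With voom values the difference was -0.034 for mesothelial markers, and with the stricter filter 0.078 for steroid receptors and metabolism. Without the 2 libraries rich in 18S it was -0.65 for neutrophil markers, -1.89 for mesothelial markers, -2.65 for fat cell markers, 0.51 for embryo and trophoblast markers, -0.62 for MHC class II genes, -0.072 for prostaglandin synthesis and receptors and -0.82 for immediate early genes. Leaving out each library gave a range of -0.087 to 0.37 for endometrial stroma markers (0.12 with all), -0.75 to 0.37 for macrophage and dendritic cell markers (-0.092 with all) and -0.25 to 1.00 for neutrophil markers (0.26 with all). Values ran from -0.54 to 1.45 for red blood cell markers (0.46 with all), -0.96 to 0.89 for mesothelial markers (0.056 with all) and -1.38 to 2.61 for fat cell markers (0.40 with all). It was -0.19 to 0.37 for embryo and trophoblast markers (-0.076 with all), -0.28 to 0.11 for decidualization genes (-0.13 with all) and -0.44 to 0.055 for extracellular matrix and remodelling genes (-0.20 with all). They ran from -0.64 to 0.51 for interferon-stimulated genes (-0.12 with all), -0.41 to 0.79 for MHC class II genes (0.28 with all) and -0.79 to 0.40 for inflammatory cytokines and chemokines (-0.18 with all). The span was -0.52 to 0.83 for immediate early genes (0.072 with all), -0.085 to 0.084 for respiratory chain genes (-0.031 with all) and -0.19 to 0.65 for mitochondrially encoded genes (0.30 with all). The values were -0.57 to 0.39 for replication-dependent histone genes (-0.17 with all).

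Log2 fold changes of opposite sign were 0.059 for Pgr with library totals alone, -0.39 for Cfd with limma-voom, and 0.072 for Pgr and -0.011 for Cfd without the 2 libraries rich in 18S. With the smooth muscle covariate they were -0.44 for Hoxa10, -0.38 for Hoxa11, 0.014 for Hbegf, -0.49 for Hand2, 1.48 for Ltf, -0.066 for Eef1a1 and -0.042 for Gm13456. Leaving out each library gave -0.18 to 0.69 for Hoxa10 (0.13 with all), -0.14 to 0.56 for Hoxa11 (0.20 with all) and -0.00306 to 0.19 for Esr1 (0.12 with all). Values ran from -0.52 to 0.11 for Pgr (-0.14 with all), -1.08 to 1.16 for Ltf (-0.20 with all) and -2.33 to 1.15 for Rn18s-rs5 (-0.81 with all). It was -0.12 to 0.35 for Gm13456 (0.16 with all). The cause was not tested, and none of these genes passed the threshold. Depth limits the rare transcripts, since 3 counts correspond to 0.213 to 0.256 CPM.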

Other observations

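Chosen after results were seen were the scan of gene families, the smooth muscle covariate, and the tests on epithelial loss, on single libraries, on muscle carried along and on blood, and the choice of the glycosylation enzymes. The criteria of the tests on epithelial loss, on single libraries, on muscle and on blood were revised after a first result. For glycosylation the criterion was written before the test, and its bound was set aside after the result. Among 435 families of at least 5 tested genes with a common symbol stem, camera with the preset correlation called 7 higher and 12 lower, and with an estimated correlation 0. With the estimated correlation the smallest adjusted p over these families was 0.9995. That form told no family from another, so its adjusted p decides nothing about a single family. Levels are mean ± SD with the agonist against without it (n = 3). Naip genes, sensors of bacterial proteins in inflammasomes, were lower in 5 of 5 members (adjusted p = 5.68e-05; adjusted p = 0.9995 with an estimated correlation). Naip5 measured 53.6 ± 22.1 against 173 ± 48.0 CPM and Naip1 38.8 ± 35.9 against 163 ± 87.4 CPM. These genes are close relatives in a cluster, so reads can be shared between them. Mucin genes, which code for the glycoproteins of mucus and of the epithelial surface, were lower in 7 of 7 members (adjusted p = 5.85e-05; adjusted p = 0.9995 with an estimated correlation). Muc4 measured 219.8 ± 169 against 926 ± 388 CPM, Muc20 25.3 ± 11.4 against 96.0 ± 11.7 CPM and Muc13 7.99 ± 10.9 against 83.9 ± 51.6 CPM.

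Interferon-induced transmembrane genes, which restrict virus entry, were higher in 5 of 5 members (adjusted p = 6.93e-04; adjusted p = 0.9995 with an estimated correlation). Ifitm3 measured 1004 ± 108 against 460.3 ± 86.8 CPM and Ifitm1 363 ± 115 against 98.6 ± 74.0 CPM. Gimap genes, GTPases of lymphocytes and endothelium, were higher in 8 of 8 members (adjusted p = 4.28e-04; adjusted p = 0.9995 with an estimated correlation). Gimap4 measured 26.1 ± 10.0 against 12.6 ± 2.04 CPM and Gimap6 31.8 ± 7.93 against 19.7 ± 3.05 CPM. Membrane serine proteases of the Tmprss family were lower in 6 of 8 members (adjusted p = 0.00742; adjusted p = 0.9995 with an estimated correlation). Tmprss4 measured 155 ± 76.6 against 479 ± 58.9 CPM and Tmprss11g 13.97 ± 13.0 against 80.8 ± 32.6 CPM. Keratins were lower in 16 of 20 members under TMM factors and 14 of 20 under library totals alone (adjusted p = 5.68e-05; adjusted p = 0.9995 with an estimated correlation). Krt84 measured 17.3 ± 14.4 against 796 ± 86.3 CPM and Krt13 21.4 ± 12.5 against 85.8 ± 6.90 CPM. How far the mucins, Tmprss genes and keratins follow epithelial content was not tested. The epithelial markers were lower in 15 of 18 members, with a median fitted log2 fold change of -0.55 and all 3 agonist libraries below the others. Nor was it tested how far the Gimap genes follow lymphocyte and endothelial content. NK and T cell markers were higher in 9 of 9 tested members, endothelial markers in 14 of 14 and B and plasma cell markers in 5 of 6. None of the genes of these families passed the adjusted threshold over all genes tested.

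Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The other splits have no set direction, so the larger of their counts of genes higher and lower at an unadjusted p under 0.05 was set against each count of the real split. The highest other was 1043. The real split gave 691 genes higher, which 3 of the 10 splits reached, itself included, and 844 lower, which 2 reached. Setting a single direction against the larger count of each other split favours the other splits. Counted in both directions together, the real split gave 1535 genes and the highest other 1504. Past the adjusted threshold the real split gave 0 genes and the highest other 0. With a real count of 0 all 10 splits are as large by definition, so this count decides nothing. The real split called 12 lists, the highest other 18, and 5 of the 10 called as many. For the estrogen-induced genes, the split of no-agonist library 1 and agonist libraries 2 and 3 against the rest gave an absolute mean log2 difference of 1.69, against 1.63 in the real split.

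The estrogen-induced genes were lower by a median of -1.88 on the log2 scale. A loss of epithelial cells as the whole cause stays open: the epithelial markers had a median of -0.55, a difference of -1.33 (95% bootstrap interval over members -1.80 to -0.27), but by library the gap between the levels of the lists differed by -1.19 (95% t interval over libraries -3.55 to 1.17). Without no-agonist library 3 the mean log2 difference was -1.04 (-1.57 to -0.45) against -1.63 with all, and whether most of the difference may rest on this library stays open. With the smooth muscle level as a covariate the median was -0.99 (-1.37 to -0.24), so a share that goes with muscle content stays open too. The bootstrap intervals treat correlated members (estimated correlation 0.46) as independent and leave out the spread between libraries. An effect of the treatment on estrogen response is one possible biological explanation among others and was not tested.

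Smooth muscle markers were lower by a mean log2 difference of -1.02. Muscle carried along in differing amounts regardless of treatment stays open: the group means lay 1.13 pooled within-group SDs apart with overlapping libraries, which a treatment effect with this spread would also give. No-agonist library 3 alone stays open too, since without it the difference was -0.53 (95% bootstrap interval over members -0.63 to -0.42), an interval on both sides of the bound set for this test. The interval treats strongly correlated members (estimated correlation 0.900) as independent. It leaves out the spread between libraries. An effect of the agonist on the muscle itself was not tested.

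B and plasma cell markers were higher by a mean log2 difference of 1.14, with separated libraries. Blood carried along may contribute: the red blood cell markers differed by 0.46 on the log2 scale, 0.321 pooled within-group SDs, with overlapping libraries, a difference too uncertain to decide. More such cells in the tissue with the agonist stays open as the biological explanation, and the 6 tested members cannot separate cell number from expression per cell.

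A hypothesis drawn from Mgat4c and Mgat4a was that enzymes of glycosylation are lower as a group. Of 73 tested members, the 2 genes that prompted the hypothesis included, 42 were lower, 57.5% (exact 95% interval 45.4 to 69.0%), which includes the 47.8% of all tested genes. The bound set beforehand counted this against the hypothesis, but an interval on both sides of that share decides nothing, so it stays open. With p adjusted over these members alone, 8 were lower and 4 higher. The camera p was 0.0468 with the preset and 0.332 with an estimated correlation.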
